A study of Mus musculus with 9 samples.

How the data were processed

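Olfactory bulb RNA of male mice, 9 samples in all, was measured on Clariom S arrays, 3 per group, after 7 days of inhaled vehicle, 1% linalyl acetate or 10% linalyl acetate. Groups were taken from the sample titles, which match the source names and the growth protocol. The design text names a human array, a human cell line and another compound, and the descriptions of 5 samples give oral and injected treatments. These texts look left over from another study, which the sources used here do not settle, and they were not used for grouping. Vehicle replicate 3, without which genes pass the adjustment, is 1 of the 5: its description gives an injection of LPS (lipopolysaccharide), while those of vehicle replicates 1 and 2 give saline. The probe set identifiers end in a mouse suffix.

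The authors normalized the arrays with SST-RMA (signal space transformation robust multi-chip analysis) in Transcriptome Analysis Console 4, and the deposited signal table gives log2 values rounded to 2 decimals for 22206 probe sets, from 2.18 to 19.93. The deposited series matrix gives log2 values of the same arrays with 5 decimals for 28846 probe sets, 6640 of them controls. The largest difference between these tables was 0.07 log2 units, and 98.3% of values lay within a rounding tolerance of 0.0051. In the signal table, 27 cells of 1 array held calendar dates in place of numbers; they were decoded and lay within 0.00518 of the matrix. The authors' comparison tables give group averages on the log2 scale, a signed fold change score, and p-values with an adjusted p-value from limma with a one-way model and empirical Bayes moderation. The authors' group averages are not arithmetic means of the 3 arrays (gaps up to 2.54 log2 units), so all averages here come from the signal table. The authors' stated criterion was an unadjusted p under 0.05 and a fold change over 2, with a detection level of 0.05 and a separation of positive from negative controls of at least 0.7. That separation, computed here as an area under the curve, was 0.788 to 0.808 per array. The median of 5222 negative control probe sets was 6.87 to 7.12 log2 units and their 95th percentile 10.8 to 11.1, so they gave no usable floor and no detection filter was applied. The genome build is not given in the sources used here, and no coordinates are reported.

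Of the 22206 probe sets, 836 with several gene symbols and 3 with none were left out of the main tests, and 21367 with 1 symbol were tested, which carry 21154 distinct symbols. A limma means model (limma 3.58.1, statmod 1.5.0, R 4.3.3) was fitted to all 9 arrays, with moderated contrasts for 1% against vehicle, 10% against vehicle and 10% against 1%, a moderated F test over the 3 groups, and Benjamini-Hochberg adjustment over all tested genes at 0.05. The model had 6 residual and 5.27 prior degrees of freedom. Genes past the authors' criterion were counted from the same fit. Gene lists, 38 in all (early activity genes, neuronal and glial cell types of the bulb and neighbouring tissue, stress, inflammation, metabolism, clock and RNA classes), were tested with limma camera at a preset correlation of 0.01 and a minimum of 5 measured genes, adjusted over the lists of each comparison. Camera with an estimated correlation and limma fry were run beside it. In 1 case a list member was matched through a synonym. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so single genes have no such test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the plots.

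Up to 12 genes per direction and comparison were named. They were genes past the adjustment whose groups did not overlap, then genes past the criterion without overlap by absolute log2 difference, then genes with an unadjusted p under 0.05 without overlap by p, up to at least 6. The higher group's mean had to reach the median of all genes, and this rule counted predicted genes but did not name them. Later passages name a few predicted genes outside the rule. The rule also took the 4 members with the smallest p of each described list and 14 chosen genes of activity, transmission, stress and inflammation, whatever their p. Not all of these are printed: several lists show fewer members or none, and some of the 14 genes are not given between doses. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

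The pipeline was tested on simulated data with 200 changed genes in the 10% group: at the adjusted threshold it recovered 60% of them at a 2-fold change, 99.5% at 4-fold and 100% at 16-fold. It also called 6, 16 and 8 unchanged genes. The simulated noise was independent between genes and held no outlying arrays. These shares therefore do not give the recovery in the real arrays, where genes vary together and single arrays stand apart. The criterion took 37 to 45 of the unchanged genes in these runs, and 34 to 43 genes in a simulated comparison with no change.

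The alternatives were a replicate block, each pair of groups alone, each array left out in turn, array weights, a trended robust prior, filters on dim genes at the 25th and 50th percentile, quantile normalization, median centring, the series matrix, an unmoderated contrast, an adjusted p under 0.1, a fold over 1.5, and the authors' tables. A term for arrays of higher cortex marker signal and the fit without those arrays were added after the data were seen. Shared vehicle arrays were modelled with 100 simulations of unchanged groups. Whether equal replicate numbers pair the samples is not stated in the labels, and no pairing was assumed.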

Results

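Gene expression was measured in the olfactory bulb of male ICR mice, an outbred stock, on Clariom S arrays with mouse probe sets. The mice breathed 1 of 3 aerosols by whole-body inhalation over 7 days: the vehicle, 1% of the detergent Tween, or linalyl acetate at 1% or at 10%. The sample titles do not say whether the linalyl acetate aerosols also held Tween, so a difference in Tween between groups cannot be excluded. Linalyl acetate is a volatile ester of lavender oil. Per the labels, mice were housed singly, and a tail suspension test, which scores immobility under restraint, followed 30 min of inhalation. The deposited description of vehicle replicate 3 gives an LPS (lipopolysaccharide) injection, at odds with its title, and the grouping follows the titles. Each group held 3 arrays, 9 in all, and the errors below measure the spread between samples; whether each sample was 1 animal is not given in the sources used here. Median log2 signal per array was 6.92 to 6.98. Pearson's r between pairs of arrays, across genes that are not independent replicates, was 0.985 to 0.992, with a median of 0.988 within groups and 0.989 between groups. The number of arrays limits the precision: the median SE of a difference between groups was 0.21 on the log2 scale. In 1 array of each group (vehicle replicate 3, 1% replicate 2 and 10% replicate 2), the mean of 17 marker genes of cortex and anterior olfactory areas stood apart, at 9.83, 9.74 and 9.78 log2 units. The other 6 arrays lay between 8.999 and 9.33. These 17 genes include Nr4a2, which also belongs to the early gene list below.

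The first comparison set 1% linalyl acetate against vehicle. Immediate early genes, which neurons transcribe soon after stimulation, had lower means after 1% linalyl acetate in 26 of the 27 listed, with a mean log2 difference of −1.22. Nr4a3 (probe set TC0400000529.mm.2), an orphan nuclear receptor, averaged 10.70 ± 0.86 against 13.42 ± 1.34 log2 units (SD, n = 3), a difference of −2.72 ± 0.75 (SE) or 6.60-fold. Fosb, a subunit of the AP-1 transcription factor, was lower by a log2 difference of −2.24 ± 0.64, Nr4a2 by −2.09 ± 0.49 and Fosl2 by −1.06 ± 0.35. Fos (TC1200000833.mm.2) averaged 6.41 ± 0.40 against 8.92 ± 2.504 (SD, n = 3), a difference of −2.51 ± 0.89 (SE). The 1% arrays (6.62, 6.66 and 5.95) and vehicle replicate 3 (6.08) lay below the negative control medians of 6.87 to 7.12. Those medians set no detection floor, but values this low are dim, so the size of the Fos difference is uncertain. Egr1, a zinc-finger early transcription factor, differed by −1.94 ± 0.79, and Arc, a postsynaptic plasticity protein, by −1.50 ± 0.57. The vehicle arrays did not lie together: relative to their mean, the list stood at 0.46, 0.75 and −1.21 in vehicle replicates 1, 2 and 3, and at −1.27, −0.81 and −1.59 in the 1% arrays.

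The limma camera test with its preset correlation called the early genes lower in the 1% group at an adjusted p of 7.8e-19. The adjusted p = 0.979 with an estimated correlation, and the limma fry test gave an adjusted p of 0.998. Of the 27 genes, 0 passed over all genes in limma, 3 passed adjusted over the list alone, 16 had an unadjusted p under 0.05, and 6 had groups that did not overlap, against a chance share of 10%. Without vehicle replicate 3 the list mean was −1.83, and 7 genes, all early genes, passed the adjustment over all genes, among them Fos at −3.93 ± 0.31 and Npas4 at −3.20 ± 0.37. With all arrays Npas4 differed by −1.80 ± 0.89 and had no unadjusted p under 0.05. The size of its difference is also uncertain, since it was dim in vehicle replicate 3 (5.45) and in 1% replicates 1 and 3 (6.44 and 5.65). Vehicle replicate 3 was the vehicle array with the lowest list mean, so leaving it out had to enlarge the list difference. Fos, Arc and Egr1 lost an unadjusted p under 0.05 without vehicle replicate 1 (−1.56, −1.04, −1.52), vehicle replicate 2 (−2.04, −1.11, −1.35) or 1% replicate 3 (−2.28, −1.22, −1.45). Arc and Egr1 also lost it without 1% replicate 1, at −1.42 and −1.87.

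**Figure D1:**
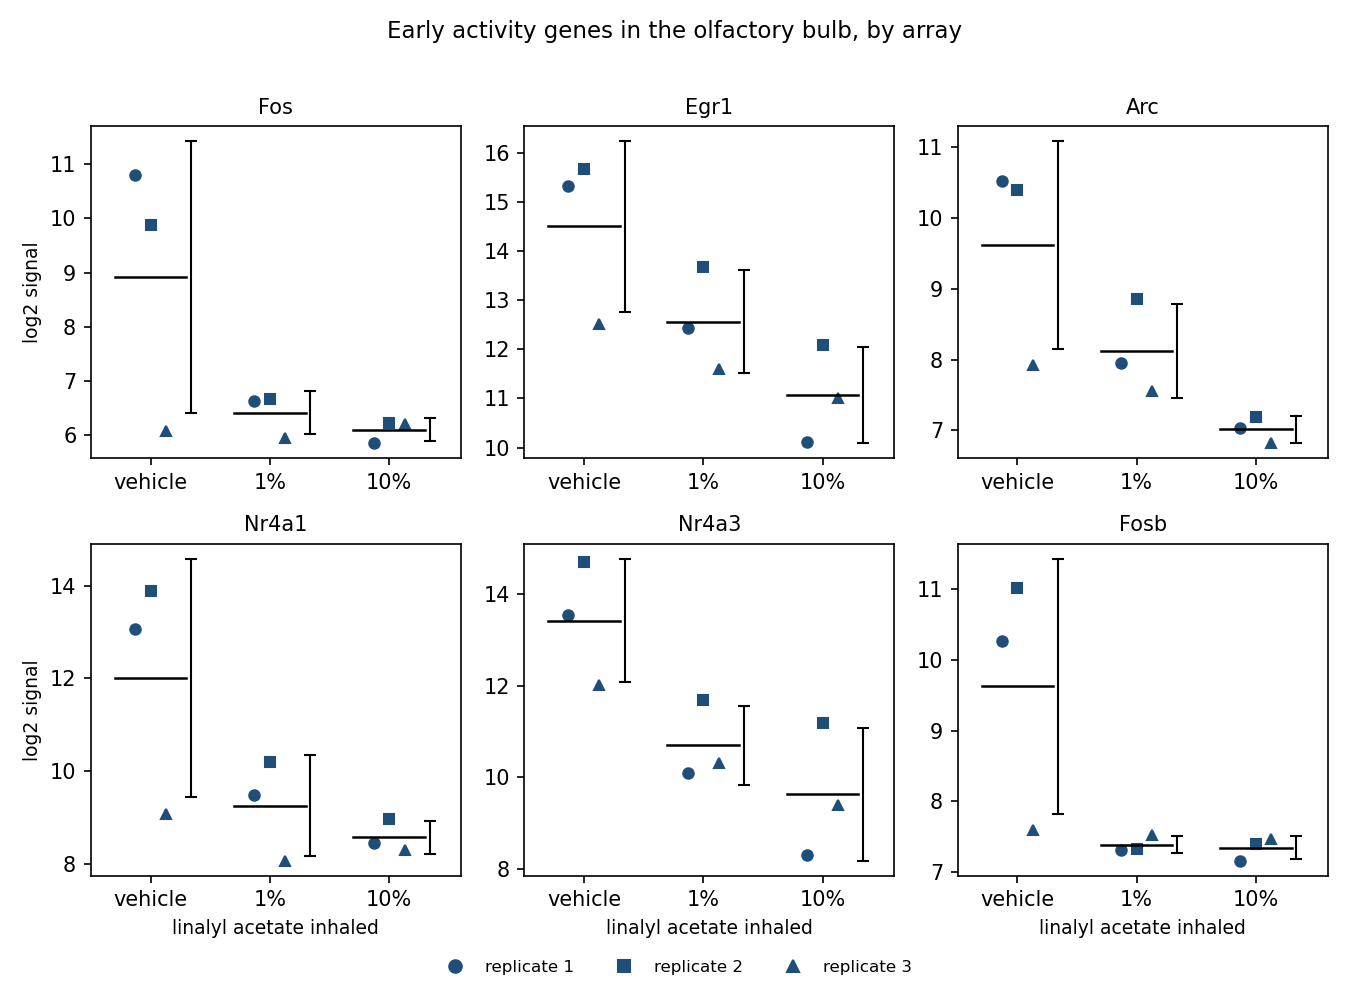
Log2 signal of 6 immediate early genes on each array by group; points are arrays with the shape giving the replicate, lines are group means and bars beside them are SD (n = 3). For Fos, vehicle replicates 1 and 2 lay at 10.81 and 9.87, vehicle replicate 3 at 6.08, and the linalyl acetate arrays between 5.85 and 6.66.

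Among the other genes at 1%, Hist1h4c (TC1300001640.mm.2), a histone H4 gene, averaged 12.21 ± 0.75 against 10.35 ± 0.20 log2 units (SD, n = 3), a difference of 1.86 ± 0.33 (SE). It was the highest among genes taken by the naming rule, which leaves out predicted genes and genes whose groups overlap. The histone list as a whole held 38 higher and 24 lower members, with an adjusted p of 0.616 (limma camera); 1 member passed adjusted over the list alone and 0 over all genes. Sla, a Src-like adaptor, was higher by 1.16 ± 0.28, Stk19 by 1.10 ± 0.32, and Paqr8, a membrane progestin receptor, by 1.02 ± 0.28. AI506816 was higher by 1.503 ± 0.31, and Trappc11, a subunit of a vesicle tethering complex, by 0.96 ± 0.20. Lower genes included the protocadherin Pcdhb10 at −1.04 ± 0.23, Mrs2, a mitochondrial magnesium channel, at −1.02 ± 0.23, and Mrps10, a mitochondrial ribosomal protein, at −0.63 ± 0.16. Fkbp5, a glucocorticoid-induced cochaperone, was higher by 0.70 ± 0.25, and lost an unadjusted p under 0.05 without vehicle replicate 2 (0.48) or 1% replicate 3 (0.60). Chosen genes of transmission and inflammation had no unadjusted p under 0.05 with all arrays. Bdnf differed by 0.96 ± 0.68, and passed that level without vehicle replicate 3 (1.58) or the 3 arrays of higher cortex signal (1.37). Crh differed by −0.27 ± 0.18, Th by −0.08 ± 0.44, Gad1 by 0.09 ± 0.34 and Npy by −0.06 ± 0.25. Ntrk2 differed by 0.03 ± 0.15, Il1b by −0.14 ± 0.22 and Tnf by −0.12 ± 0.17.

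Markers of olfactory sensory neurons, whose axons end in the bulb, had lower means after 1% linalyl acetate in 16 of 18, with a mean log2 difference of −0.29. Omp, the olfactory marker protein, averaged 9.68 ± 0.98 against 10.88 ± 0.95 (SD, n = 3), a difference of −1.20 ± 0.53 (SE), and Stoml3, a stomatin-like protein of their cilia, differed by −1.05 ± 0.50. The limma camera test called the list lower at an adjusted p of 0.0182, and the adjusted p = 0.979 with an estimated correlation. In limma, 0 members passed over all genes, 0 passed adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list was lowest in 1% replicate 2, an array of higher cortex signal, at −0.60 from the vehicle mean; its call was lost without that array (mean −0.14, adjusted p 0.498, limma camera), without vehicle replicate 1 (−0.15, 0.412) and without the 3 arrays of higher cortex signal (−0.17, 0.204). Omp was the member with an unadjusted p under 0.05, and lost it without vehicle replicate 1 (−0.73), vehicle replicate 2 (−1.18), 1% replicate 1 (−1.35), 1% replicate 2 (−0.65), 10% replicate 1 or 10% replicate 2 (both −1.20).

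Clock genes at 1% held 11 higher and 8 lower members of 19, with an adjusted p of 0.0695 (limma camera) and an adjusted p = 0.979 with an estimated correlation. In limma, 0 members passed over all genes, 2 passed adjusted over the list alone, and 7 higher and 1 lower had an unadjusted p under 0.05. The repressor Ciart was higher by 0.85 ± 0.22, the nuclear receptor Nr1d1 by 0.71 ± 0.19 and Per3 by 0.54 ± 0.18, and the repressor Nfil3 was lower, at −0.78 ± 0.25. Markers of olfactory ensheathing glia were lower in 11 of 13, with a mean of −0.27 and an adjusted p of 0.0695 (limma camera); 0 passed adjusted over the list alone and 0 over all genes, and 0 had an unadjusted p under 0.05. In the arrays of higher cortex signal this list was lowest of its group in 3 of 3 groups.

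Across 21367 genes, 0 passed a Benjamini-Hochberg adjusted p under 0.05 in limma at 1% (lowest 0.998), and the authors' own limma table held 0 as well (lowest 0.9996). An unadjusted p under 0.05 was reached by 731 genes, 375 higher and 356 lower, where 1068 would be expected with no difference. The authors' criterion, an unadjusted p under 0.05 and a fold over 2, took 35 genes, 12 higher and 23 lower, in this fit, and 48 single-symbol genes in the authors' table, 30 of them shared. The groups did not overlap for 9.22% of genes, against 10% by chance. Of 38 lists, 2 were called, both lower; 0 were called with an estimated correlation and 0 by fry. Without vehicle replicate 3, the counts were 7 genes past the adjustment, 118 past the criterion and 7 lists; without the 3 arrays of higher cortex signal, 11 genes passed the adjustment and 139 the criterion. The list count was 1 without vehicle replicate 1, 4 without 1% replicate 1 and 4 without 1% replicate 3.

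The comparison of 10% linalyl acetate with vehicle showed the same group of genes at lower means. Of the 27 early genes, 26 were lower, with a mean log2 difference of −1.54. Nr4a3 averaged 9.63 ± 1.45 against 13.42 ± 1.34 log2 units (SD, n = 3), a difference of −3.79 ± 0.75 (SE) or 13.9-fold. Its relative Nr4a1 differed by −3.45 ± 0.98, Egr1 by −3.43 ± 0.79, Arc by −2.61 ± 0.57, Nr4a2 by −2.29 ± 0.49 and Fosb by −2.28 ± 0.64. Egr2 differed by −1.45 ± 0.42, Ptgs2, the inducible prostaglandin synthase, by −1.24 ± 0.50, Gadd45b by −1.16 ± 0.32, and Fosl2 by −1.05 ± 0.35. Fos averaged 6.10 ± 0.21 against 8.92 ± 2.504 (SD, n = 3), a difference of −2.82 ± 0.89 (SE), and Npas4, a factor induced by calcium entry, differed by −2.39 ± 0.89. For both genes the 10% arrays and vehicle replicate 3 lay below the negative control medians, so the size of these 2 differences is uncertain. Relative to the vehicle mean, the list stood at −1.77, −1.29 and −1.54 in the 10% arrays, below vehicle replicate 3 at −1.21.

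The limma camera test called the early genes lower in the 10% group at an adjusted p of 3.9e-26. The adjusted p = 0.346 with an estimated correlation, and the limma fry test gave an adjusted p of 0.559. Of the 27 genes, 0 passed over all genes in limma, 21 passed adjusted over the list alone, 21 had an unadjusted p under 0.05 and 11 had groups that did not overlap, against a chance share of 10%. Without vehicle replicate 3 the list mean was −2.14, and 12 genes passed the adjustment over all genes, 11 of them early genes, with Fos at −4.24 ± 0.31 and Arc at −3.45 ± 0.32. The remaining gene was Tiparp, at −1.73 ± 0.23, named after its value was seen. As at 1%, leaving out this array had to enlarge the list difference. An unadjusted p under 0.05 was lost for Ptgs2 without vehicle replicate 2 (−0.84), 10% replicate 1 (−0.85) or 10% replicate 3 (−1.29). It was lost for Npas4 without vehicle replicate 1 (−1.60), vehicle replicate 2 (−1.77) or 10% replicate 3 (−2.30).

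Other genes lower at 10% were Cyr61, a secreted matricellular protein, by −1.07 ± 0.22, and Kitl, the ligand of the Kit receptor, by −1.01 ± 0.31. Genes higher at 10% included AI506816 by 1.13 ± 0.31, Perm1, a muscle regulator of energy metabolism, by 1.02 ± 0.29, Nvl, a nucleolar ATPase, by 1.01 ± 0.34, and Trappc11 by 0.88 ± 0.20. Ifit3b, an interferon-induced gene, averaged 8.79 ± 0.04 against 7.98 ± 0.10 (SD, n = 3), a difference of 0.81 ± 0.15 (SE), and the transcription factor Deaf1 differed by 0.74 ± 0.17. Fkbp5 was higher by 0.87 ± 0.25. Nvl lost an unadjusted p under 0.05 without vehicle replicate 3 (0.70) or 10% replicate 1 (0.77). Crh, the stress neuropeptide, differed by −0.46 ± 0.18, with an unadjusted p under 0.05 lost without vehicle replicate 2 (−0.36), 10% replicate 1 (−0.40) or 10% replicate 2 (−0.39). Th, the dopamine synthesis enzyme, differed by −0.33 ± 0.44, and passed that level without 10% replicate 3 (−0.86). Bdnf differed by 0.22 ± 0.68, Gad1 by 0.09 ± 0.34, Omp by 0.06 ± 0.53, Npy by 0.27 ± 0.25, Ntrk2 by −0.11 ± 0.15, Il1b by 0.18 ± 0.22 and Tnf by −0.07 ± 0.17.

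Heat shock and unfolded protein response genes were lower at 10% in 22 of 24, with a mean log2 difference of −0.33 and an adjusted p of 1.1e-05 (limma camera). The adjusted p = 0.894 with an estimated correlation. In limma, 0 members passed over all genes, 0 passed adjusted over the list alone and 3 had an unadjusted p under 0.05. Xbp1, a transcription factor of the unfolded protein response, differed by −0.85 ± 0.31, Atf3 by −0.54 ± 0.23, the chaperone Calr by −0.61 ± 0.27 and the cochaperone Dnajb1 by −0.90 ± 0.42. Atf3 also belongs to the early gene list. Among vehicle arrays, the list stood at −0.19, −0.02 and 0.21 from the vehicle mean, the highest in replicate 3, the array of higher cortex signal, and at −0.52, −0.33 and −0.13 in the 10% arrays.

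Cholesterol synthesis genes were lower at 10% in 18 of 23, with a mean log2 difference of −0.18 and an adjusted p of 0.00761 (limma camera). The adjusted p = 0.346 with an estimated correlation. The sterol demethylase Cyp51 differed by −0.45 ± 0.20 and Msmo1 by −0.65 ± 0.32. Endothelial and pericyte markers were lower in 15 of 19, with a mean of −0.20 and an adjusted p of 0.00974 (limma camera). The adjusted p = 0.948 with an estimated correlation. The pericyte receptor Pdgfrb differed by −0.46 ± 0.16, Rgs5 by −0.52 ± 0.28 and the endothelial receptor Flt1 by −0.47 ± 0.25. Cytosolic ribosomal protein genes were higher in 55 of 68, with a mean of 0.12 and an adjusted p of 0.00969 (limma camera). The adjusted p = 0.948 with an estimated correlation. Rpl11 differed by 0.39 ± 0.17 and Rpl18, in the opposite direction, by −0.49 ± 0.23. In each of these 3 lists, limma took 0 members over all genes, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. The cholesterol call was lost without vehicle replicate 3 (mean −0.15, adjusted p 0.0851, limma camera) or 10% replicate 1 (−0.12, 0.256), and the ribosomal call without vehicle replicate 3 (0.10, 0.0882) or 10% replicate 2 (0.06, 0.450). The vascular call was lost without vehicle replicate 2 (mean −0.18, adjusted p 0.0620, limma camera), 10% replicate 2 (−0.17, 0.0620) or 10% replicate 1 (−0.03, 0.679). Without the 3 arrays of higher cortex signal all 3 calls were lost: cholesterol at a mean of −0.17 (adjusted p 0.0682, limma camera), vascular at −0.19 (0.131) and ribosomal at 0.03 (0.878). The clock list at 10% was mixed, with 9 higher and 10 lower members (adjusted p 0.812, limma camera; 0 adjusted over the list alone and 0 over all genes, 3 higher and 2 lower at an unadjusted p under 0.05). Ciart was higher by 0.74 ± 0.22 and Nr1d1 by 0.59 ± 0.19, and Nfil3 and Arntl differed by −0.78 ± 0.25 and −0.75 ± 0.29.

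**Figure D2:**
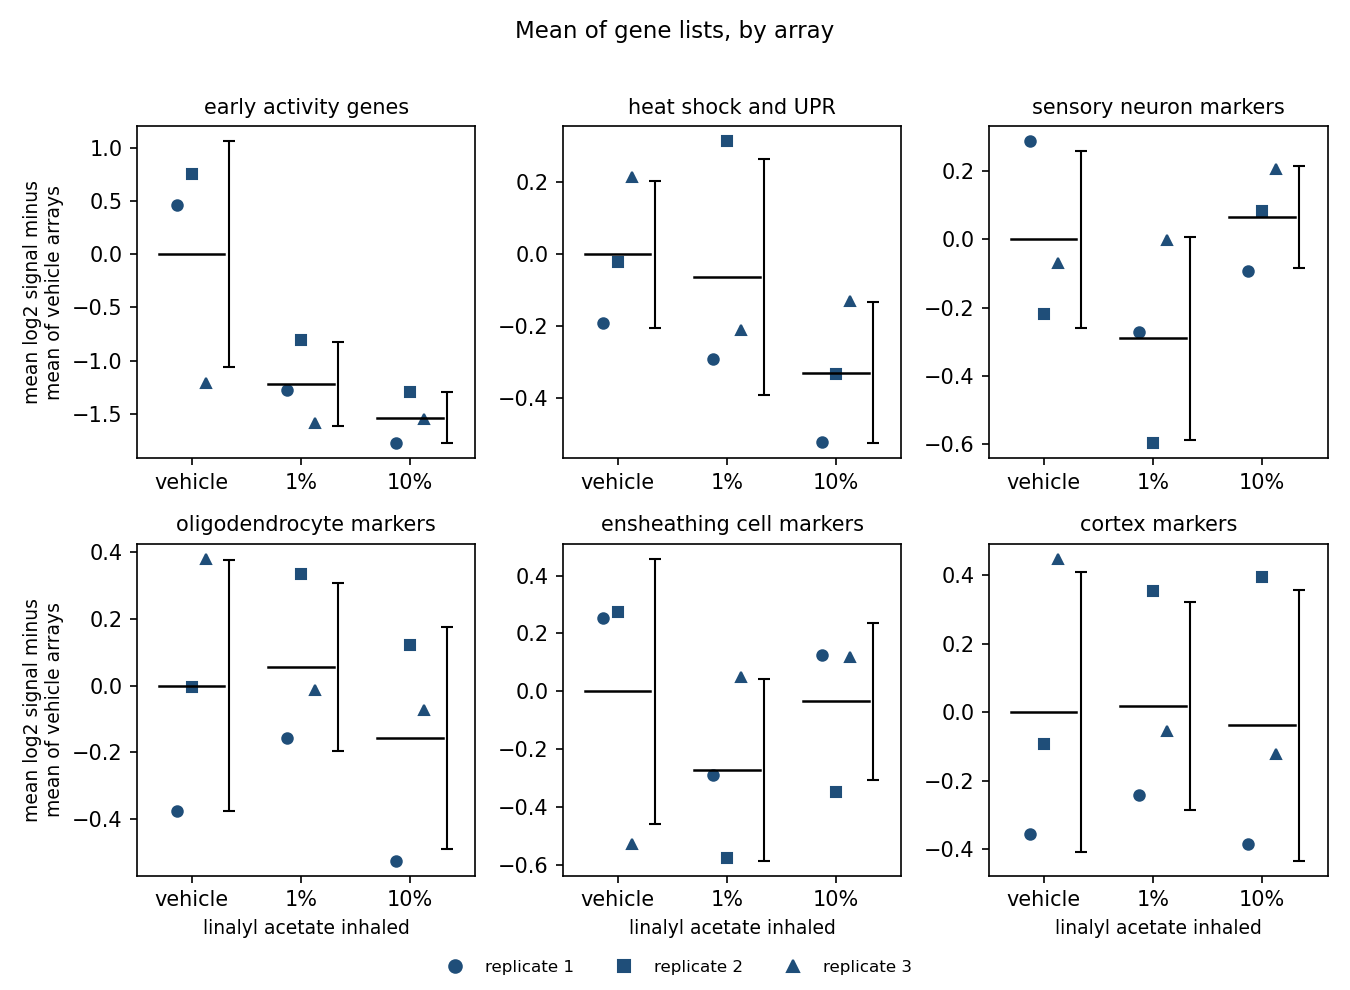
Mean log2 signal of 6 gene lists on each array, relative to the mean of the vehicle arrays; points are arrays with the shape giving the replicate, lines are group means. The early gene list stood at 0.46 and 0.75 in vehicle replicates 1 and 2 and between −0.81 and −1.77 in the other arrays, vehicle replicate 3 included.

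Across 21367 genes, 0 passed the adjustment in limma at 10% (lowest adjusted p 0.998), and 0 in the authors' limma table (lowest 0.9997). An unadjusted p under 0.05 was reached by 807 genes, 441 higher and 366 lower, against 1068 expected. The criterion took 42 genes, 17 higher and 25 lower, and 45 in the authors' table, 34 of them shared. The groups did not overlap for 7.46% of genes, against 10% by chance. Of 38 lists, 5 were called, 1 higher and 4 lower; 0 were called with an estimated correlation and 0 by fry. Without vehicle replicate 3, 12 genes passed the adjustment and 67 the criterion; without 10% replicate 3, 81 passed the criterion. Without 10% replicate 1, Obp2b, an odorant-binding protein, at 3.46 ± 0.33, and Zfp125 at 3.46 ± 0.25 passed the adjustment, both named after their values were seen, and 3 lists were called. Without vehicle replicate 1, 9 lists were called. Without the 3 arrays of higher cortex signal, 12 genes passed the adjustment, all early genes, and 92 the criterion.

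The comparison of the 2 doses set 10% against 1% linalyl acetate. Markers of olfactory sensory neurons were higher at 10% in 14 of 18, with a mean log2 difference of 0.36. Stoml3 averaged 12.42 ± 0.65 against 10.97 ± 1.02 log2 units (SD, n = 3), a difference of 1.45 ± 0.50 (SE). Omp differed by 1.26 ± 0.53, the cyclic nucleotide-gated channel subunit Cnga4 by 0.61 ± 0.24 and the G protein subunit Gng13 by 0.51 ± 0.20. The limma camera test gave an adjusted p of 0.00102, and the adjusted p = 0.774 with an estimated correlation. In limma, 0 members passed over all genes, 0 passed adjusted over the list alone and 4 had an unadjusted p under 0.05. The call was lost without 1% replicate 2, an array of higher cortex signal (mean 0.20, adjusted p 0.188, limma camera), and without all 3 such arrays (0.19, 0.202). Without 1% replicate 2 Omp differed by 0.71 and lost an unadjusted p under 0.05, as it did without 10% replicate 3 at 0.92.

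Heat shock and unfolded protein response genes were lower at 10% than at 1% in 22 of 24, with a mean of −0.27 and an adjusted p of 4.2e-04 (limma camera). The adjusted p = 0.774 with an estimated correlation. Xbp1 differed by −0.70 ± 0.31, and Chac1, a stress-induced glutathione-degrading enzyme, lay the other way at 0.65 ± 0.22. Oligodendrocyte markers were lower in 15 of 18, with a mean of −0.21 and an adjusted p of 0.0312 (limma camera). The adjusted p = 0.774 with an estimated correlation. The myelin genes Mobp and Mbp differed by −0.82 ± 0.41 and −0.37 ± 0.26. In limma, both lists had 0 members past the adjustment over all genes and 0 adjusted over the list alone; the counts at an unadjusted p under 0.05 were 2 for heat shock genes and 0 for oligodendrocyte markers. Oligodendrocyte markers were highest of their group in the arrays of higher cortex signal in 3 of 3 groups. The heat shock call was lost without 1% replicate 2 (mean −0.08, adjusted p 0.406, limma camera), 10% replicate 1 (−0.17, 0.0909) or the 3 arrays of higher cortex signal (−0.08, 0.305). The oligodendrocyte call was lost without 1% replicate 2 (mean −0.07, adjusted p 0.512, limma camera) or 10% replicate 1 (−0.03, 0.870). The early genes were lower in 22 of 27, with a mean of −0.31 and an adjusted p of 0.0689 (limma camera). The adjusted p = 0.774 with an estimated correlation; 0 passed adjusted over the list alone and 0 over all genes, and 0 had an unadjusted p under 0.05. Arc differed by −1.11 ± 0.57, Egr1 by −1.497 ± 0.79 and Fos by −0.31 ± 0.89. Arc passed an unadjusted p of 0.05 without vehicle replicate 3 (−1.11) or the 3 arrays of higher cortex signal (−0.83). Egr1 passed it without vehicle replicate 3 (−1.497), 1% replicate 3 (−1.98), 10% replicate 2 (−2.002) or the 3 arrays of higher cortex signal (−1.45). The list passed without vehicle replicate 2 (adjusted p 0.0359, limma camera), vehicle replicate 3 (8.6e-04), 1% replicate 3 (0.00153) or 10% replicate 2 (0.0153). It also passed without the 3 arrays of higher cortex signal (mean −0.23, adjusted p 0.0231, limma camera). Vehicle arrays are not part of this contrast, so leaving out 1 of them kept the differences and changed only the estimated spread.

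Of single genes between the doses, Paqr8 was lower at 10% by −1.35 ± 0.28, the relaxin receptor Rxfp1 by −1.16 ± 0.42, smooth muscle actin Acta2 by −1.01 ± 0.28, AI464131 by −0.81 ± 0.21, the tachykinin Tac2 by −0.74 ± 0.21 and Mrpl35 by −0.71 ± 0.20. The transporter Abca8a was higher by 1.37 ± 0.47, Cd55b, a complement regulator, by 1.13 ± 0.35, Nvl by 1.07 ± 0.34 and Acsf2 by 0.87 ± 0.19. Bdnf differed by −0.75 ± 0.68, and had an unadjusted p under 0.05 only without 10% replicate 2 (−1.64) among single arrays. Without the 3 arrays of higher cortex signal it also passed that level, at −1.425. Of 21367 genes, 0 passed the adjustment in limma (lowest adjusted p 0.999), 642 had an unadjusted p under 0.05 (367 higher, 275 lower) where 1068 would be expected, and 23 passed the criterion (12 higher, 11 lower). The groups did not overlap for 7.10% of genes, against 10% by chance. Of 38 lists, 3 were called, 1 higher and 2 lower; 0 were called with an estimated correlation and 0 by fry. Without 1% replicate 2, Gdpd3 passed the adjustment at −3.55 ± 0.36 and 0 lists were called. Without 10% replicate 1, Obp2b at 3.08 ± 0.33 and Zfp125 at 3.24 ± 0.25 passed; these 3 genes were named after their values were seen. The criterion took 38 genes without 1% replicate 1, 41 without 1% replicate 3, 93 without 10% replicate 2, 35 without 10% replicate 3 and 89 without the 3 arrays of higher cortex signal. The list count was 10 without vehicle replicate 3 or 10% replicate 3, 5 without 1% replicate 1, 8 without 1% replicate 3 and 7 without 10% replicate 2. Abca8a lost an unadjusted p under 0.05 without 1% replicate 1 (1.22), 1% replicate 2 (1.19) or 10% replicate 3 (0.92), Rxfp1 without 1% replicate 2 (−0.90) or 10% replicate 1 (−0.67), and Stoml3 without 1% replicate 2 (0.86) or 10% replicate 3 (1.07).

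Both doses were then set side by side. The genes past the criterion in the same direction at both doses numbered 19, of which 16 were lower and 3 higher, and 0 went in opposite directions. The lower genes included 14 of the early gene list, such as Fos, Egr1, Arc, Nr4a1 and Dusp1, together with Glra4 and Gm7068; the higher ones were AI506816, Gm14744 and 5430402E10Rik. The last 2 were uneven within doses: in 10% replicate 1 they lay at 5.20 and 5.08, within the vehicle range, and in 1% replicate 2 at 6.28 and 6.48, against 9.70 to 11.39 in the other 4 linalyl acetate arrays. Both comparisons share the 3 vehicle arrays, which alone makes their changes alike. Simulated unchanged groups with shared vehicle arrays gave a median of 9 such genes (2 to 15) when genes varied independently. When the residuals kept their correlation between genes, 14 of 100 simulations gave as many, and 5 of 100 gave as many lower genes. The correlation of log2 differences across genes, which are not independent, was 0.585, against medians of 0.504 and 0.566 in the same simulations. The 3 vehicle arrays are too few to split between the comparisons. The count was 12 without vehicle replicate 1, 7 without vehicle replicate 2, 35 without vehicle replicate 3, 11 without 1% replicate 1, 7 without 1% replicate 3 and 33 without the 3 arrays of higher cortex signal.

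A test over the 3 groups together took 0 of 21367 genes past the adjustment (limma F test, lowest adjusted p 1.00), with 631 at an unadjusted p under 0.05 where 1068 would be expected. Without vehicle replicate 3 it took 8 genes, without 10% replicate 1 it took 2, and without the 3 arrays of higher cortex signal it took 11.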

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

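The probe sets of several symbols were set aside beforehand; the tests of explanations in this part were chosen only after the results were seen. Among 836 probe sets with several gene symbols, which no comparison above uses, 2 were higher than vehicle past the authors' criterion at 1% linalyl acetate. The probe set shared by Mup2 and Mup1, which encode urinary odorant carriers, was higher by a log2 difference of 1.497 ± 0.59 (SE, n = 3). The probe set shared by Nlrp5-ps and the vomeronasal receptor genes Vmn1r90 and Vmn1r181 was higher by 1.17 ± 0.34. In the same comparison 1 probe set was lower past the criterion, that of Zfp33b and Gm20385, at −1.48 ± 0.48; at 10% against vehicle there were 0, and between doses 2 were higher and 8 lower. In limma, 0 of the 836 passed the adjustment in any comparison, and 41, 26 and 32 had an unadjusted p under 0.05.

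Early activity genes were lower in the linalyl acetate arrays as a whole by a list mean of −1.38 (exact two-sided permutation p = 0.0238 over 84 splits of 3 vehicle and 6 linalyl acetate arrays), although vehicle replicate 3 lay among the latter. The list was taken to this permutation test after its lower means at both doses were seen. Its p is not adjusted for the choice of this list among all those tested. The smallest p that these splits can give is 0.0119. The permutation p thus restates the difference already seen and is no independent sign of an effect. Uneven carry-over of cortical tissue is argued against only by the opposite directions in the arrays of higher cortex signal, 1 per group. There the list stood −1.82 from the rest of the vehicle group but 0.63 and 0.36 from the rest at 1% and 10%. Among the other arrays the difference was −2.15, though leaving out vehicle replicate 3 had to enlarge it. Their cortex means overlapped (9.03 and 9.29 against 8.999 to 9.33), but the cortex list holds the early gene Nr4a2. Among these arrays Nr4a2 lay at 12.25 and 12.78 in vehicle and at 8.82 to 10.02 with linalyl acetate. This lifts the vehicle cortex means, so their overlap is no test of carry-over. An exchange of vehicle replicate 3 with a linalyl acetate array needs a partner with high values, but the highest linalyl acetate array minus the lower of vehicle replicates 1 and 2 was −1.27, beyond the SD of 0.34 of the linalyl acetate arrays. A single wrong label stays open for a concrete reason: the deposited description of vehicle replicate 3 gives an LPS injection, and if that were true, the vehicle means and the difference of −1.38 would not describe vehicle alone. A different time of day at collection cannot be told apart from an effect of linalyl acetate. The mean of 8 clock output genes, such as Dbp and Nr1d1, was 0.55 higher in the linalyl acetate arrays. That set was put together after the data were seen, and 7 of the 8 already had an unadjusted p under 0.05 at 1%. Per1, which was lower (−0.27 at 1% and −0.54 at 10%), was left out, so the value is no test. A set of 4 genes of the opposite phase, such as Arntl and Clock, differed by −0.16 (exact two-sided permutation p = 0.179). The clock gene Nfil3, lower by −0.78 at both doses, was in neither set.

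All 7 listed genes for odorant-binding and major urinary proteins, such as Obp2a and Mup4, had a linalyl acetate array more than 1 log2 unit above the highest vehicle array, which 0.852% of all genes did; they were picked for this. Obp2a reached 8.56 and 10.39 in 1% replicates 1 and 3 and 12.35 and 11.80 in 10% replicates 2 and 3, while vehicle arrays lay at 7.01, 4.34 and 4.76 and the 2 remaining linalyl acetate arrays at 6.01 and 5.48. More olfactory sensory neuron tissue is argued against as the only source: the marker list of these neurons stood highest in vehicle replicate 1 (0.29 from the vehicle mean), where the 7 genes averaged 5.42, and at −0.27 in 1% replicate 1, where they averaged 7.46, although it was lowest of its group in the 2 remaining arrays (−0.60 and −0.09), and the count of 0 of 18 markers is also the median of random lists. Nasal gland or epithelium carried over cannot be told apart from a response: 1 of 29 gland and epithelium markers did so, random lists of like expression gave a median of 0 and as many in 27.6% of draws, and only 2 of the 29 lay above the median of all genes. A response to the inhaled ester was not tested apart from this, and 2 of the 6 linalyl acetate arrays lacked it.

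Cortex marker genes were high in 1 array of each group, by a mean of 0.61 over the rest of their group, with Sst at 13.18, 13.43 and 13.43 in vehicle replicate 3, 1% replicate 2 and 10% replicate 2. A difference in array quality stays open: the separation of control probe sets was lowest of its group in 0 of these arrays, but highest in 3 of 3, so a technical measure goes with the pattern. The depth of the dissection is a candidate explanation: the ensheathing glia list, whose cells lie at the bulb's surface, differed by a mean of −0.57 and was lowest of its group in 3 of 3 groups (exact one-sided permutation p = 0.037 over 27 choices of 1 array per group), and oligodendrocyte markers were highest in 3 of 3 by a mean of 0.47. That p is the smallest that 27 choices can give and only restates the 3 of 3, for a list chosen after the arrays were seen. Markers of meninges (mean −0.45), GABAergic interneuron genes (−0.34) and dopaminergic periglomerular genes (−0.30) were also lowest in 3 of 3. Synaptic vesicle genes (0.38) were highest in 3 of 3, so the pattern is not particular to surface and myelin markers. Vehicle replicate 3 alone also stood 1.47 above the other vehicle arrays in striatum markers, with Drd1 at 8.45. No biological explanation was tested, since each group held 1 such array.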

How the results depend on the processing

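The tests with a term for cortex marker signal and without the 3 arrays of that signal were chosen only after the data were seen. Genes past the adjustment numbered 0 in each comparison and in the F test under every other setting that kept all arrays, the replicate block included. Without the 3 arrays of higher cortex signal they were 11 at 1%, 12 at 10%, 0 between doses and 11 in the F test. Of these arrays, vehicle replicate 3 left out alone gave 7 at 1% and 12 at 10%. Leaving out 1% replicate 2 or 10% replicate 2 alone gave 0 in both comparisons. The calls against vehicle thus went mainly with the loss of vehicle replicate 3, and are no sign that cortex signal hid them. Leaving out 1 array gave 0 to 7 at 1%, 0 to 12 at 10%, 0 to 2 between doses and 0 to 8 in the F test. Genes past the criterion (35, 42 and 23) became 38, 45 and 26 with the replicate block and ranged from 33 to 118, 30 to 81 and 21 to 93 with 1 array left out. They were 139, 92 and 89 without the 3 arrays, and 255, 278 and 227 at a fold of 1.5, by construction. The trended robust prior gave 21 at 1% and 25 at 10%; the cause was not tested. The filter at the median gave 22 and 26, from fewer genes tested. Genes shared by both doses (19) were 21 with the replicate block, 8 with the trended robust prior, 33 without the 3 arrays, 46 at a fold of 1.5, and 7 to 35 with 1 array left out. Lists called (2, 5 and 3) were 2, 5 and 4 with the replicate block, and 0, 0 and 0 with an estimated correlation and with fry, which allow for the correlation of list members. At 1% they were 5 with the filter at the median, 1 with that at the 25th percentile and 4 with the cortex term; at 10%, 3 without the 3 arrays; between doses, 7 with the filter at the median, 8 with the cortex term, 8 without the 3 arrays and 10 with the 2 groups alone. The cause was not tested for these. With 1 array left out, 1 to 7, 3 to 9 and 0 to 10 lists were called. No named gene or list reversed: of single-gene results with all but the single-array alternatives, 919 kept their side of an unadjusted p under 0.05, 24 lost it and 12 gained it, and of list results 236 kept their side of an adjusted p under 0.05, 27 lost it and 10 gained it. With 1 array left out these were 682, 39 and 8 for genes and 163, 14 and 12 for lists. The authors' tables hold no comparison of the doses, so that alternative was not run there. Equal replicate numbers did not pair the arrays: the correlation of deviations from group means had a median of 0.0127 (−0.161 to 0.279), and 3 of 9 arrays correlated best with their own number. Negative controls overlapped the signal of most genes, so dim genes are least certain.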

Other observations

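The splits of the samples were planned beforehand, and the single genes of this part were picked only after the data were seen, with no test chosen for them afterwards. Inflammatory genes of the NF-kB pathway held 9 higher and 18 lower members at 1% (adjusted p 0.266, limma camera) and 14 higher and 13 lower at 10% (0.880). Interferon response genes were higher at 10% than at 1% in 20 of 26 (adjusted p 0.0748, limma camera), with a mean of 0.14. Microglia markers were lower at 10% than in vehicle in 16 of 20, with a mean of −0.15 (adjusted p 0.156, limma camera). Mitral and tufted cell genes, which mark the bulb's output neurons, were lower at 10% than at 1% in 11 of 12, with a mean of −0.30 (adjusted p 0.0748, limma camera). Their list is not particular to these neurons. Its member Tbr1 went with cortex signal, at 12.11, 12.32 and 12.54 in the 3 arrays of higher cortex signal and 9.52 to 10.99 in the others. GABAergic interneuron genes stood at a mean of 0.03 at 1% and 0.01 at 10%, and dopaminergic periglomerular genes at −0.22 and −0.29 (adjusted p 0.579 and 0.147, limma camera). The latter list holds the early gene Nr4a2, at −2.09 and −2.29, and its medians were −0.08 and −0.12.

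The 1095 olfactory receptor genes stood at means of 0.02 at 1% (adjusted p 0.689, limma camera) and 0.00 at 10% (0.880), and the 306 vomeronasal receptor genes had adjusted p of 0.720 and 0.878. Enzymes for foreign compounds and esters held 11 higher and 19 lower members at 1% (adjusted p 0.481, limma camera) and 12 and 18 at 10% (0.812). Glucocorticoid response genes, Fkbp5 among them, held 11 higher and 10 lower at 1% (adjusted p 0.938, limma camera) and 10 and 11 at 10% (0.812). Haemoglobin probe sets shared by paralogs had lower means at 10% than at 1% without passing the adjustment: both probe sets of Hba-a1 and Hba-a2 differed by −1.14 (SE 0.25 and 0.23; adjusted p 0.459, limma), and that of Hbb-bs and Hbb-b1 by −1.30 ± 0.53 (0.986). The erythrocyte marker list had a mean of −0.09 (adjusted p 0.422, limma camera). Some genes took high and low values within every group, such as Cwc22, from 6.80 in 1% replicate 3 to 15.64 in 10% replicate 1, with 7.06 and 14.06 in vehicle replicates 1 and 2. Prss22 lay between 7.79 and 8.67 in the vehicle arrays and at 3.93 in 1% replicate 1 and 10% replicate 2 and 4.53 in 10% replicate 3, with 8.20, 7.76 and 8.26 in 1% replicates 2 and 3 and 10% replicate 1 (10% against vehicle −2.75 ± 1.16). Bpifb9b, a secreted protein of nasal tissue, lay at 12.32, 12.55 and 14.00 in vehicle replicate 1, 1% replicate 3 and 10% replicate 3, and between 6.49 and 9.67 elsewhere.

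The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. Past the adjustment in limma, the real splits gave 0 genes at 1%, 10% and between doses, which 10 of 10 splits must match, so these counts say nothing on chance; the highest other splits gave 0, 0 and 1. Past the criterion, the real counts were 35, 42 and 23, the highest others 155, 166 and 173, and 5, 5 and 8 of 10 splits gave as many. Lists called were 2, 5 and 3, the highest others 13, 13 and 12, and 9, 6 and 8 of 10 splits gave as many. Some other splits thus called several times the real count, and the cause was not tested. For the F test over 3 groups, 100 of 100 splits gave at least the real count of 0, as they must, and the highest other gave 293; at an unadjusted p under 0.05 the real count was 631, the highest other 2683, and 90 of 100 splits gave as many. For the genes shared by both doses, 17 of 100 assignments gave as many as the real 19, the highest 87, so chance cannot be excluded there either.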
